A study of Rattus norvegicus with 6 samples.

How the data were processed

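Small RNA was profiled in 6 samples of rat primary skeletal muscle cells on day 11 of differentiation, 3 untreated and 3 exposed to IL-8. Per the labels' protocols, total RNA had RNA integrity numbers between 9.5 and 10.0, was spiked with control RNAs, labelled with Cy3 and hybridised to 1 array per sample. Groups were taken from the sample titles, which give control or treated and a replicate number. The growth protocol in the labels describes IL-8 for all 6 samples, while titles, agent labels and the design text call 3 of them untreated; the titles were followed.

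The deposited values are fluorescence intensities of the array spots on a linear scale, per the file headers extracted with Agilent Feature Extraction 10.10.1.1 with background subtraction and spatial detrending and without normalization between arrays. Each array has 15095 spots, of which 14380 belong to 1730 probes for 719 rat miRNAs. Deposited beside the array files is a set of intensities with a column for each array. All of its 15095 values per array equalled the software's total probe signal within a relative tolerance of 0.0001, so it is on a linear scale, not centred and not normalized between arrays. Its column medians were -0.529, -1.35 and -1.17 for the control arrays and 0.307, -0.802 and -1.18 for the IL-8 arrays. Background subtraction leaves dim probes near or below 0, so their ratios are unstable. The processed spot signal already carries these steps, and any error in them enters all values here. No spot of a rat miRNA was saturated.

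The spots of a probe were averaged without spots that the software called outliers. Each array was divided by its 75th percentile over the 264 probes well above background on all 6 arrays, values were floored at a log2 level of -5.03 relative to that percentile, and log2 was taken. The miRNAs with a value at the floor numbered 11 of 167. A probe counted as well above background on an array when the software said so for more than 50% of its spots. A miRNA was tested when at least 1 of its probes was well above background on all 3 arrays of a group, and its value was the mean of those probes; 36 miRNAs had 1 such probe. This left out 552 miRNAs. Dividing by a percentile removes any change shared by all miRNAs, so each change is relative to the other miRNAs of the array. Where a miRNA was detected in 1 group only, the bound was the detected group's mean over the other group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal; no fold is given where it is under 1.

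IL-8 was compared with control by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with version 1.17.8 of the data.table package for reading, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes carry 95% confidence intervals from the same fit. Of 19 miRNA lists, 13 had at least 3 tested members and were tested with camera at an inter-miRNA correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists. Array measures were compared by exact two-sided permutation tests, and correlations by permutation tests with 100000 resamples, two-sided. Array design files gave probe positions on rn4; gene annotation of that build was not used here. Which control probes measure labelling and which hybridisation was taken from general knowledge of the spike-in kit, since the array files give only their target names.

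Groups, tests, lists, alternatives and the rule for naming miRNAs were set before the data were examined. The lists came from general knowledge: muscle-enriched miRNAs, miRNAs described to promote or to restrain myoblast differentiation, the clusters and families miR-17~92, miR-15 with miR-16, miR-195 and miR-322, let-7, miR-34, miR-99 with miR-100 and miR-125, miR-23 with miR-27 and miR-24, miR-29, miR-30 and Dlk1-Dio3, inflammation-responsive miRNAs, markers of fibroblasts and smooth muscle, blood, endothelium, epithelium and neural cells, and the hypoxia miRNA miR-210. The rule names up to 10 rises and 10 falls past the threshold whose groups do not overlap, every tested muscle-enriched miRNA, the 5 miRNAs of highest mean, and 2 to 4 members with the smallest p of each other tested list. The rule left the number per list open. It was 3 at first and was set to 2 after the values under the alternatives had been seen, to shorten the account of them. That choice took the named miRNAs from 49 to 37 and their values of opposite sign under an alternative, leave-outs aside, from 82 to 53; in neither count was any such value past the threshold. Further members, array outcomes and features outside the rule are named in places and were chosen after their values were seen.

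The alternatives were other scalings (75th percentile over all probes, median, quantile, none, spike-ins), normexp background correction with an offset of 50, other probe summaries, filters and floors, the deposited total probe signal, other limma settings, a replicate block and leaving out each array. Scaling on labelling spike-ins alone and removal of a probe GC trend were added after seeing the data. The steps were tested on simulated data: in 50 sets of 167 miRNAs with 40 changed between IL-8 and control, limma recovered 71% of changes of 1.2-fold, 99.1% of 1.5-fold and 99.9% of 2-fold, and 3.09% of its calls were unchanged miRNAs. A list of 28 members shifted 1.2-fold was called in 100% of the sets, and 0.308% of list tests were called with no shift. The simulated miRNAs were drawn independently of each other, so these shares do not hold for lists whose members vary together. In the real data the estimated correlation was 0.0912 for the Dlk1-Dio3 list and 0.420 for the miR-30 list. These simulations began from scaled log2 values, so they did not cover scaling, floor and filter.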

Results

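Rat primary skeletal muscle cells (RSkMC), taken from the limb muscle of newborn animals, were held for 11 days in differentiation medium with 2% horse serum. The cells were either left untreated (control, n = 3 samples) or given interleukin-8 (IL-8), a chemokine that attracts neutrophils, at 1 ng/ml (n = 3 samples). MicroRNA (miRNA) was measured in total RNA on 1-colour Agilent arrays carrying 1730 probes for 719 rat miRNAs. The control arrays had 154, 156 and 164 miRNAs well above background, and the IL-8 arrays had 180, 169 and 168. Of the 719 miRNAs, 152 were well above background on all 6 arrays and 537 on none, and 167 entered the test. Correlations between arrays over these 167 miRNAs ran from r = 0.993 to r = 0.999 across miRNAs, which are not independent replicates. All control arrays lay on one slide and all IL-8 arrays on another, so slide and group cannot be told apart in any comparison. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

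The main comparison asked whether IL-8 alters the miRNA profile of the differentiating cells. IL-8 cultures had higher levels of miR-338-3p, miR-551b-5p, miR-411-3p, miR-181a-5p and miR-181a-1-3p, and lower levels of miR-210-3p, miR-132-3p, miR-6216, miR-129-1-3p and miR-129-2-3p. The changes were small: miR-338-3p, encoded in an intron of Aatk, rose 1.53-fold (95% CI 1.24 to 1.89), and it was the only one of the 10 above 1.5-fold. This fold is uncertain, since 1 of its 2 probes was well above background on only 1 of 3 control arrays. With the brightest probe or the filter on all 6 arrays its log2 change was 0.54 in place of 0.62, and 0 miRNAs passed 1.5-fold, nor did any without control replicate 1 or any 1 of the IL-8 arrays. The smallest p belonged to miR-210-3p, the miRNA best known for its induction by hypoxia-inducible factor, which fell to 0.705-fold of control (95% CI 0.652 to 0.764). The miRNAs with the brightest probes, among them miR-21-5p and miR-143-3p, did not pass the test. By limma with Benjamini-Hochberg adjustment over 167 miRNAs, 5 miRNAs rose and 5 fell at adjusted p under 0.05. At unadjusted p under 0.05 there were 41, of which 23 were higher and 18 lower with IL-8. The values of the groups did not overlap for 50 of the 167 miRNAs (29.9%). The average over all splits of the arrays into 3 and 3 is 10%. A single split can lie far from that average because miRNAs vary together, and the difference from it was not tested. None of the 10 changed miRNAs turned direction under any of 24 alternative settings, but the count of calls and its split did depend on the scaling between arrays. It was 15 (5 up, 10 down) with median scaling, 17 (8 up, 9 down) with quantile normalization, 24 (1 up, 23 down) with the normexp background and 51 (50 up, 1 down) without scaling. It was 31, all up, with spike-in scaling, and 6, all up, with labelling spike-ins alone, a setting chosen after seeing the data. With the 75th percentile taken over all probes limma called 0 miRNAs, with 9 at unadjusted p under 0.05. Only 269 to 326 of the 1730 probes were well above background per array, so that percentile is set by probes near background. The median log2 change over all tested miRNAs was 0.016 here, 0.24 without scaling, 0.21 with spike-in scaling and 0.18 with labelling spike-ins alone. Single arrays also moved the count, which was 29 without control replicate 3, 5 without control replicate 2, 3 without IL-8 replicate 1 and 1 (miR-210-3p) without either IL-8 replicate 2 or IL-8 replicate 3.

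**Figure D1:**
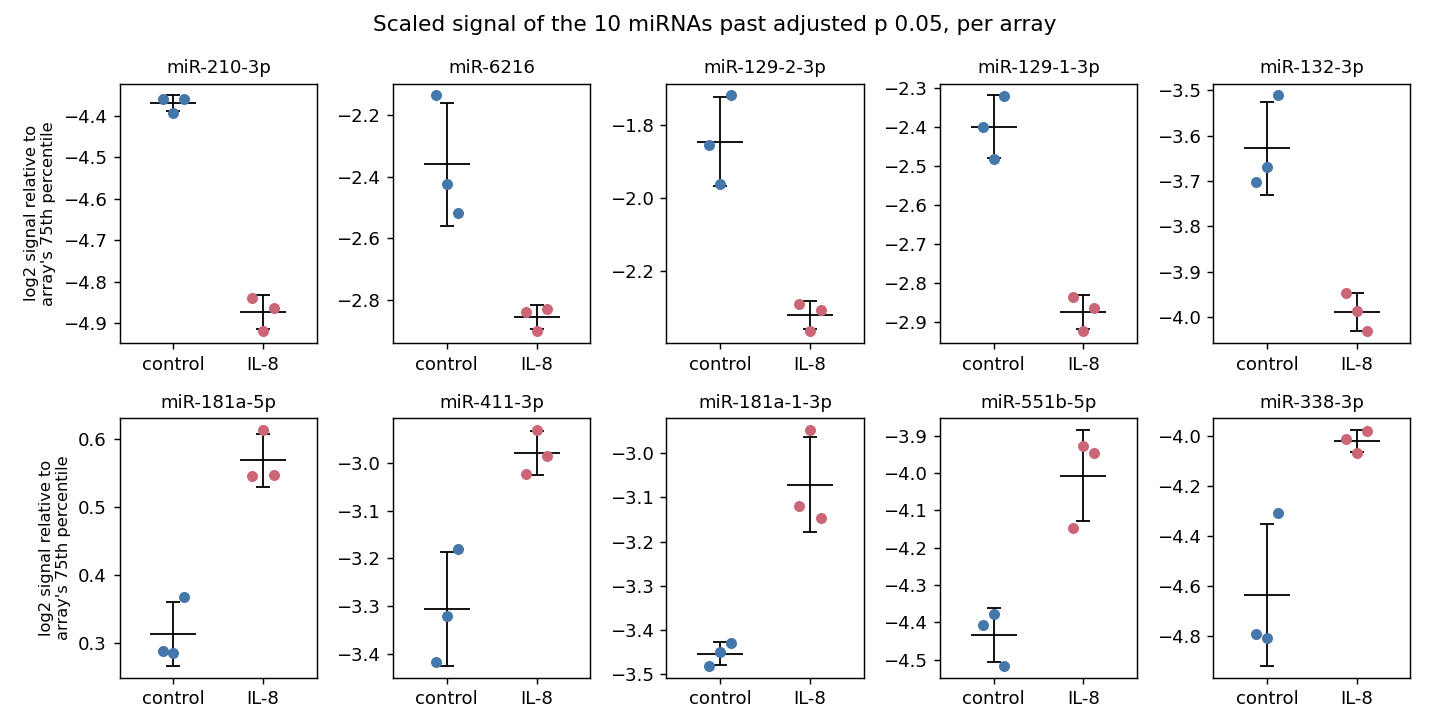
Log2 signal relative to the array's 75th percentile for the 10 miRNAs past adjusted p 0.05, with 1 point per array, the mean as a long bar and the SD as whiskers (n = 3 per group). Each panel has its own axis. The control arrays of miR-210-3p average -4.37 and its IL-8 arrays -4.87, and in each of the 10 panels the groups do not overlap.

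Among the rises, miR-338-3p went from a log2 level of -4.64 ± 0.28 (SD, n = 3) in control to -4.02 ± 0.04 (SD, n = 3) with IL-8 (limma adjusted p = 0.0371). Its probes lie on chromosome 10 at 109427033 to 109427054 in rn4, the build the array files give. miR-551b-5p, on chromosome 2 at 114095904 to 114095917, rose from -4.43 ± 0.07 to -4.01 ± 0.12 (n = 3 each), a 1.35-fold change (adjusted p = 0.0218 by limma). The 3p arm of the miR-181a-1 precursor, miR-181a-1-3p on chromosome 13 at 51132574 to 51132592, rose 1.30-fold (limma adjusted p = 0.0218), from -3.45 ± 0.03 to -3.07 ± 0.11 (n = 3 each). miR-181a-5p, which restrains the homeobox protein Hoxa11 during myoblast differentiation and whose probes map to chromosomes 3 and 13, rose 1.19-fold, from 0.31 ± 0.05 to 0.57 ± 0.04 (limma adjusted p = 0.0315, n = 3 each). miR-411-3p, a product of the imprinted Dlk1-Dio3 region on chromosome 6 at 134389396 to 134389411, rose 1.25-fold (limma adjusted p = 0.0372). All 5 rises were averaged over both probes of the miRNA, and both were higher with IL-8. The shorter probe of each lies within the sequence of the longer and on the same arrays, so this agreement is no independent support. For miR-338-3p and miR-551b-5p the dimmer probe was also well above background on only 1 and 2 of the 3 control arrays. It entered through the IL-8 arrays. With the normexp background 4 of the 5 rises were lost, miR-338-3p at a log2 change of 0.038 among them, and miR-181a-5p alone passed. That setting adds an offset of 50 to every spot before scaling, while the control means of the 2 miR-338-3p probes were 21.5 and 17.3. It shrinks changes of dim miRNAs by construction. Divided by a percentile that is higher on the IL-8 arrays, the added constant can also push dim miRNAs down. With the normexp background 23 of the 24 calls were lower. These losses therefore cannot decide whether the rises are real, and falls of dim miRNAs under that setting carry the same limit. Whether these positions are exonic or intronic was not analysed here.

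Among the falls, miR-210-3p, on chromosome 1 at 201415728 to 201415742, went from -4.37 ± 0.02 to -4.87 ± 0.04 (n = 3 each, limma adjusted p = 0.00229). miR-6216, whose probes carry no position in the array files, fell to 0.708-fold of control (limma adjusted p = 0.0309). miR-129-1-3p and miR-129-2-3p, mature forms of genes on chromosomes 4 and 3 that are best known from brain, fell to 0.720-fold and 0.719-fold (limma adjusted p = 0.00670 and 0.0130). Their probe sequences, CTTTTTGGGGTAAGGG and ATGCTTTTTGGGGTAAGG, share most bases, so these values are uncertain as separate measurements. miR-132-3p, a CREB-responsive miRNA on chromosome 10 at 62480792 to 62480806, fell to 0.779-fold, from -3.63 ± 0.10 to -3.99 ± 0.04 (limma adjusted p = 0.0218, n = 3 each). For 4 of the 5 falls only 1 of the 2 probes was well above background on all 3 arrays of a group. Both probes of miR-132-3p were, and both were lower with IL-8. Since the shorter lies within the sequence of the longer, they are not independent either. Without scaling between arrays the log2 change of miR-210-3p was -0.27 (limma adjusted p = 0.0464), while the other 4 did not pass, at -0.27 for miR-6216, -0.24 for each miR-129 form and -0.13 for miR-132-3p.

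The highest mean signals belonged to miR-21-5p, miR-143-3p, miR-125b-5p, miR-22-3p and miR-23a-3p, and none of these passed the limma test; brightness differs between probes and is no measure of relative amount. miR-21-5p, abundant in many proliferating and stromal cells, stood at 4.25 ± 0.18 in control and 4.26 ± 0.08 with IL-8 (n = 3 each). miR-143-3p, typical of smooth muscle and fibroblasts, stood at 3.78 ± 0.08 and 3.72 ± 0.05. miR-22-3p stood at 3.29 ± 0.02 and 3.16 ± 0.09, with limma adjusted p = 0.266. The 95% interval of the fold was 0.860 to 1.17 for miR-21-5p and 0.869 to 1.06 for miR-143-3p. The probes of miR-21-5p and of miR-125b-5p disagreed in direction, as did those of 24 of the 131 miRNAs with more than 1 probe in use, none of them among the 10 that changed.

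No muscle-enriched miRNA was well above background on any array. These were 14 arms of miR-1, miR-133a, miR-133b, miR-206, miR-208a, miR-208b and miR-499, miRNAs that mark differentiating and mature striated muscle. The highest signal of their 31 probes on any array was 9.23, and the lowest signal called well above background ranged from 12.3 to 17.1 between arrays. None of the 186 probe values, each an average over a probe's spots, exceeded the 95th percentile of the 434 single negative control spots of the same array. Averages spread less than single spots, so a weak signal could stay below that percentile. No change of this group with IL-8 could therefore be measured. Of the 10 fibroblast and smooth muscle miRNAs, 2 are also in the differentiation lists and 2 in the inflammation list. The 2 in the differentiation lists are the arms of miR-214, of which only miR-214-3p was detected. In contrast to the muscle-enriched miRNAs, 8 of these 10 were detected, among them miR-143-3p, miR-145-5p, miR-199a-5p, miR-214-3p and miR-21-5p. None of these 8 changed with IL-8 (median log2 change -0.024, camera adjusted p = 0.559), though with the normexp background miR-21-3p was called lower (limma adjusted p = 0.0246, with 0.0246 to 0.998 over its 24 alternatives). With no filter camera called the list lower (10 members, median -0.013, adjusted p = 0.00731), with 0.00731 to 0.972 over the 24 alternatives that keep the preset correlation. The median lay above 0 without scaling, with either spike-in scaling and without control replicate 3. Of the markers of other cell types, 0 of 12 blood cell and serum miRNAs, 0 of 3 endothelial miRNAs and 0 of 9 epithelial miRNAs were well above background on any array.

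**Figure D2:**
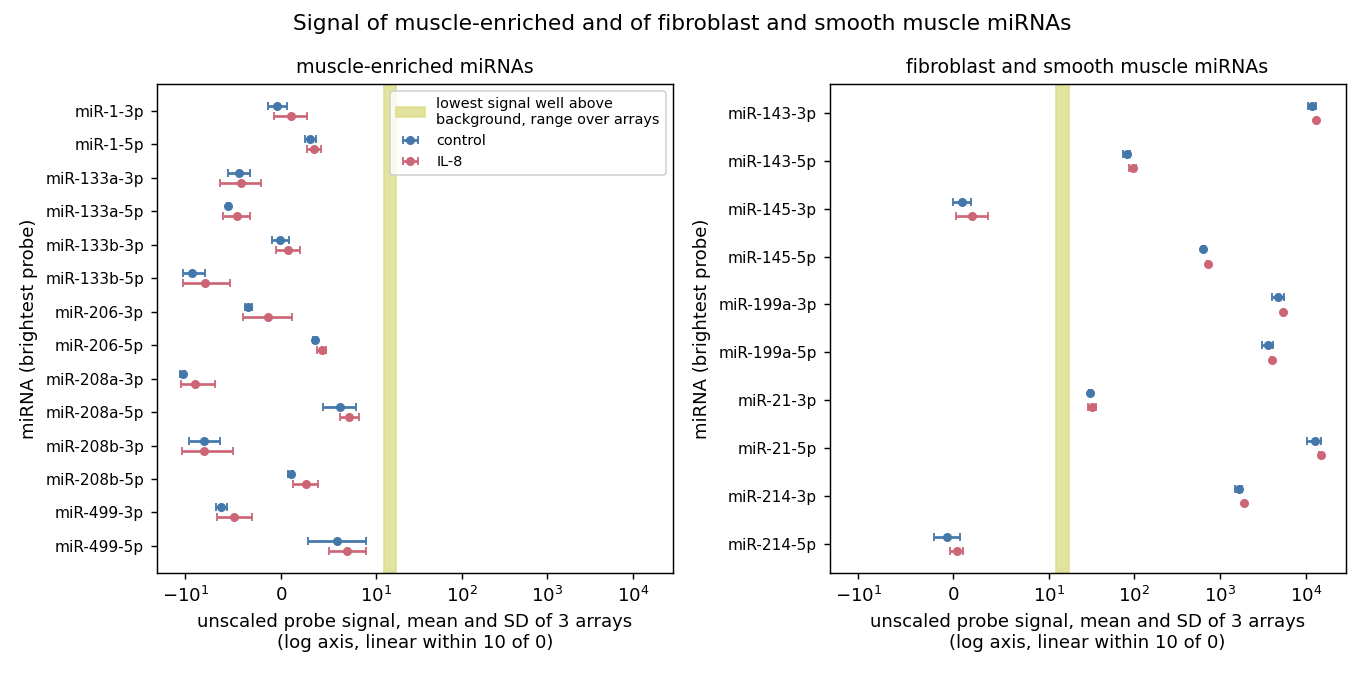
Unscaled signal of the brightest probe of each muscle-enriched miRNA (left) and each fibroblast and smooth muscle miRNA (right), as mean and SD of 3 arrays per group, on an axis that is logarithmic outside 10 of 0. The shaded band spans the lowest signal well above background on the 6 arrays, 12.3 to 17.1; all muscle-enriched miRNAs lie left of it, and 8 of 10 fibroblast and smooth muscle miRNAs lie right of it.

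Of the miRNAs described to promote myoblast differentiation, 14 of 28 were tested, and miR-181a-5p alone rose, also when adjusted over the list alone. Its relatives miR-181b-5p, miR-181c-5p and miR-181d-5p had log2 changes of 0.18, 0.19 and 0.15 that did not pass. The call of miR-181a-5p was lost in 9 of 24 alternatives, and 7 of the 14, itself included, were called in at least 1, with miR-181b-5p in 4. Outside the unscaled and spike-in settings 3 of the 14 were called, and of these miR-322-3p was lower. miR-29b-3p, a repressor of collagen genes, had a log2 change of 0.22 ± 0.13 (SE) and miR-26a-5p one of 0.13 ± 0.06 (SE), neither past the threshold. Over the list the median log2 change was 0.085 and the camera adjusted p was 0.559; the median lay below 0 with the 75th percentile over all probes. With the normexp background camera called this list higher, at a median of 0.011 (adjusted p = 0.00823, with 0.00823 to 0.802 over the 24 alternatives that keep the preset correlation). Of the miRNAs described to fall in or to restrain differentiation, 7 of 13 were tested and none passed, adjusted over the list alone or over all miRNAs. miR-222-3p, which targets the cell cycle inhibitor p27, stood at -0.16 ± 0.06 (SE) with limma adjusted p = 0.188, and miR-487b-3p at 0.15 ± 0.05 (SE). With the normexp background miR-222-3p was called lower (limma adjusted p = 0.0396, with 0.0396 to 0.998 over 24 alternatives), and without scaling or with spike-in scaling miR-487b-3p was called higher. The median of this list was -0.047 (camera adjusted p = 0.559) and lay above 0 without scaling and with either spike-in scaling.

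The imprinted Dlk1-Dio3 clusters, a maternally expressed region with many miRNA genes, were called higher as a group by camera at the preset inter-miRNA correlation of 0.01. Of its 86 miRNAs on the array 28 were tested, 22 were higher and 6 lower with IL-8, and the median log2 change was 0.074 (camera adjusted p = 0.0231). This call was lost with the estimated correlation of 0.0912 (camera adjusted p = 0.908). Only miR-411-3p passed on its own, and 0 members passed adjusted over the list alone. Its call was lost in 11 of 24 alternatives, among them the brightest probe, total gene signal, the replicate block and the omission of any 1 array other than control replicate 3. In at least 1 alternative 13 of the 28 were called, all higher. Without scaling and with either spike-in scaling, the median of all tested miRNAs itself lay at 0.18 to 0.24. Outside these settings 7 of the 28 were called. miR-379-5p, its neighbour on chromosome 6, had a log2 change of 0.21 ± 0.06 (SE), miR-411-5p one of 0.22 ± 0.06 (SE) and miR-376a-3p one of 0.32 ± 0.13 (SE). The median turned to -0.082 with the normexp background (camera adjusted p = 0.991). Under that setting the median over all tested miRNAs was also below 0, at -0.070. The miR-30 family was also called higher as a group at the preset correlation. All 6 tested of 11 members were higher, with a median log2 change of 0.17 and a camera adjusted p of 0.0375. This call too was lost with the estimated correlation, which was 0.420 (camera adjusted p = 0.908). None of its members passed alone or adjusted over the list alone; miR-30e-3p stood at 0.27 ± 0.10 (SE), miR-30c-5p at 0.19 ± 0.07 (SE) and miR-30a-5p at 0.17 ± 0.05 (SE). Each of the 6 was called higher in at least 1 alternative: miR-30a-5p in 5 of 24, among them quantile normalization, and miR-30a-5p, miR-30c-5p and miR-30e-3p with array weights and without control replicate 3. Outside the unscaled and spike-in settings 4 of the 6 were called. The miR-30 median stayed above 0 under every scaling tried. The fry test of movement in 1 direction gave an adjusted p of 0.207 for each of these 2 lists. Over 25 alternatives the camera adjusted p ran from 0.00845 to 0.991 for the Dlk1-Dio3 clusters and from 0.00844 to 0.908 for the miR-30 family. The Dlk1-Dio3 call was lost in 7 of the 25 and the median turned sign in 1; of the single arrays, only leaving out control replicate 3 ended it (adjusted p = 0.0721). The miR-30 call was lost in 14 of the 25, among them without control replicate 2 (adjusted p = 0.0714), control replicate 3 (0.119), IL-8 replicate 2 (0.0908) or IL-8 replicate 3 (0.0883).

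The miR-34 family, effectors of p53, did not pass as a list (4 of 6 tested, median log2 change -0.12, camera adjusted p = 0.627). Adjusted over the list alone, 1 member rose and 2 fell, and over all miRNAs none passed. miR-34c-5p and miR-34b-5p, neighbours on chromosome 8, had log2 changes of -0.26 ± 0.06 (SE) and -0.25 ± 0.09 (SE), with limma adjusted p = 0.0512 for miR-34c-5p. miR-34a-3p had a log2 change of 0.18 ± 0.05 (SE). Over 24 alternatives miR-34c-5p was called lower in 10 (limma adjusted p from 0.00333 to 0.998), among them median scaling, quantile normalization, normexp and array weights. miR-34b-5p was called lower in 5 and miR-34a-3p higher in 3. The fry test for change in either direction gave an adjusted p of 0.0567 for the family. The median lay above 0 without scaling and with either spike-in scaling.

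As reported, no member of the other families passed, adjusted over all miRNAs or adjusted over the list alone. The median log2 change was 0.035 over 9 tested members of miR-17~92 and its paralogous clusters (camera adjusted p = 0.641) and 0.082 over 3 members of the miR-29 family (0.627). It was -0.014 over 8 let-7 members (0.627), with miR-98-5p at -0.088 and let-7i-5p at -0.076. Over 4 members of the family of miR-15, miR-16, miR-195 and miR-322 it was -0.048 (0.851), with miR-15b-5p at 0.24 ± 0.09 (SE) and miR-322-3p at -0.14 ± 0.22 (SE). Over 8 members of the groups of miR-99, miR-100 and miR-125 it was 0.011 (0.851), and over 6 members of the clusters of miR-23, miR-27 and miR-24 -0.048 (0.627). In these last 3 lists the median, the mean and the camera test differed in sign. Each of these 6 medians took the other sign under at least 1 other scaling. Single members were called in at least 1 of 24 alternatives: 4 of the miR-17~92 list and miR-29b-3p only without scaling or with spike-in scaling, miR-15b-5p in 4, miR-24-2-5p in 3, miR-125a-3p in 2, and miR-322-3p, lower, with normexp. With the normexp background camera called the miR-29 family higher, at a median of 0.034 (adjusted p = 0.0448, with 0.0448 to 0.970 over the 24 alternatives that keep the preset correlation).

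Of the inflammation-responsive miRNAs, miR-132-3p fell and was the only one of 4 tested (13 on the array) to pass, also when adjusted over the list alone. This call was lost in 11 of 24 alternatives: no scaling, both spike-in scalings, the 75th percentile over all probes, total gene signal, no filter, the replicate block, and without control replicate 2 or any 1 IL-8 array. miR-212-3p, from the same locus, stood at 0.062 ± 0.070 (SE), miR-21-5p at 0.0069 ± 0.096 (SE) and miR-21-3p at -0.11 ± 0.084 (SE). The list had a median log2 change of -0.050 and a camera adjusted p of 0.559, and its median lay above 0 without scaling and with either spike-in scaling. miR-147 and both arms of miR-146a, miR-146b and miR-9a were not well above background on any array. Of the 2 miR-210 arms that made up the hypoxia list, miR-210-3p was tested and fell. Of 8 neural miRNAs 2 were tested, miR-128-3p at -0.15 ± 0.06 (SE) and miR-219a-5p at -0.018 ± 0.10 (SE), and neither passed, though miR-128-3p was called lower with normexp (limma adjusted p = 0.0189, with 0.0189 to 0.998 over 24 alternatives). miR-129-5p is in this list and was not well above background on any array. miR-129-1-3p and miR-129-2-3p are not in it, because their names on the array carry gene numbers.

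**Figure D3:**
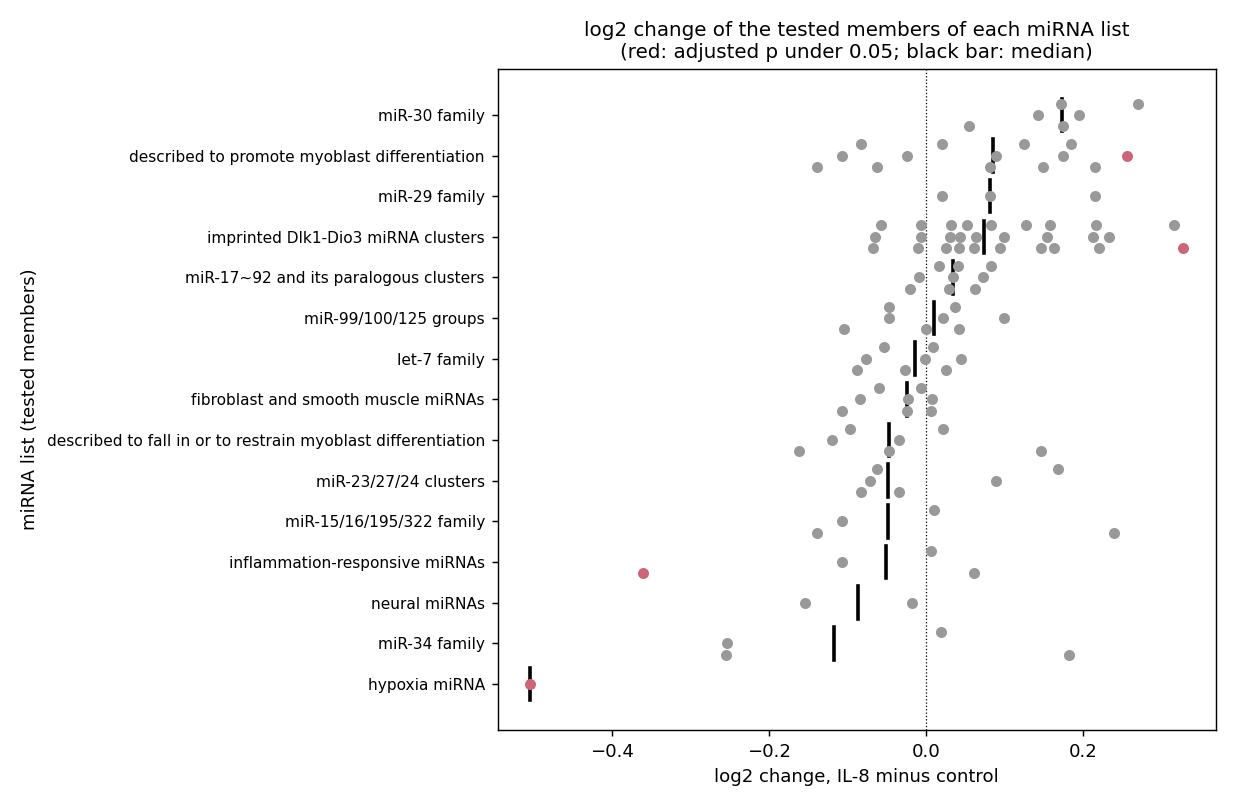
Log2 change, IL-8 minus control, of every tested member of the 15 miRNA lists with tested members; each point is 1 miRNA, a black bar is the list median and red marks adjusted p under 0.05. The miR-30 members all lie right of 0 and their median is 0.17; with the normexp background the Dlk1-Dio3 median moves from 0.074 to -0.082.

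The log2 changes of the 5p and 3p arms of a precursor correlated. Over 19 precursor names with both arms tested, this gave r = 0.694 (permutation p = 0.00089) and Spearman's rho = 0.667 (permutation p = 0.00224). Arms were matched by name, so arms whose names differ were left out, such as miR-181a-5p and miR-181a-1-3p, which both rose. These are the 2 relations computed in this family, with Benjamini-Hochberg adjusted p of 0.00178 and 0.00224. Without the 2 precursors farthest from the median of the 5p change, r was 0.654. Both arms of miR-411 were higher with IL-8 (log2 change 0.22 and 0.33), as were both arms of miR-30e (0.18 and 0.27), and 12 of the 19 pairs had the same sign. The other 7 had opposite signs, such as miR-22 with 0.042 for the 5p and -0.13 for the 3p arm, and miR-411-3p was the only arm of these pairs to pass the test. The correlation is across miRNAs, which are not independent replicates.

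miR-125b-2-3p, miR-192-5p, miR-380-3p and miR-381-3p were well above background on all 3 IL-8 arrays and on no control array, and 0 miRNAs showed the opposite. In each the IL-8 mean lay below the bound set by the dimmest probes called well above background on the control arrays, so no fold is given. None passed (lowest limma adjusted p = 0.666), but 4, 1, 3 and 3 of their 6 values lay at the floor, so the fit does not measure their change. The count was 10 without control replicate 3 and 6 without IL-8 replicate 3. The detection call of the scanner software gave 3 (let-7a-1-3p, miR-154-3p and miR-541-5p) and the demand that every spot be above background gave 1 (miR-3068-3p), with 0 of the 4 shared in either case; these names were added after their values were seen.

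Before scaling, the 75th percentile of the miRNA probes well above background was higher on every IL-8 array than on any control array. This did not hold for every single probe. The 75th percentile of log2 signal was 8.88 ± 0.09 in control and 9.11 ± 0.04 with IL-8 (SD, n = 3 each), a difference of 0.23 with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays can give. The hybridisation spike-ins stood at 14.24 ± 0.05 and 14.24 ± 0.04 (SD, n = 3 each; exact p = 0.8). The labelling spike-ins stood at 9.33 ± 0.11 and 9.38 ± 0.15 (SD, n = 3 each; exact p = 0.5). The IL-8 arrays also had 172 ± 6.66 miRNAs well above background against 158 ± 5.29 on control arrays (SD, n = 3 each; exact p = 0.1). None of 9 such array measures passed after Benjamini-Hochberg adjustment (lowest adjusted p = 0.18).

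**Figure D4:**
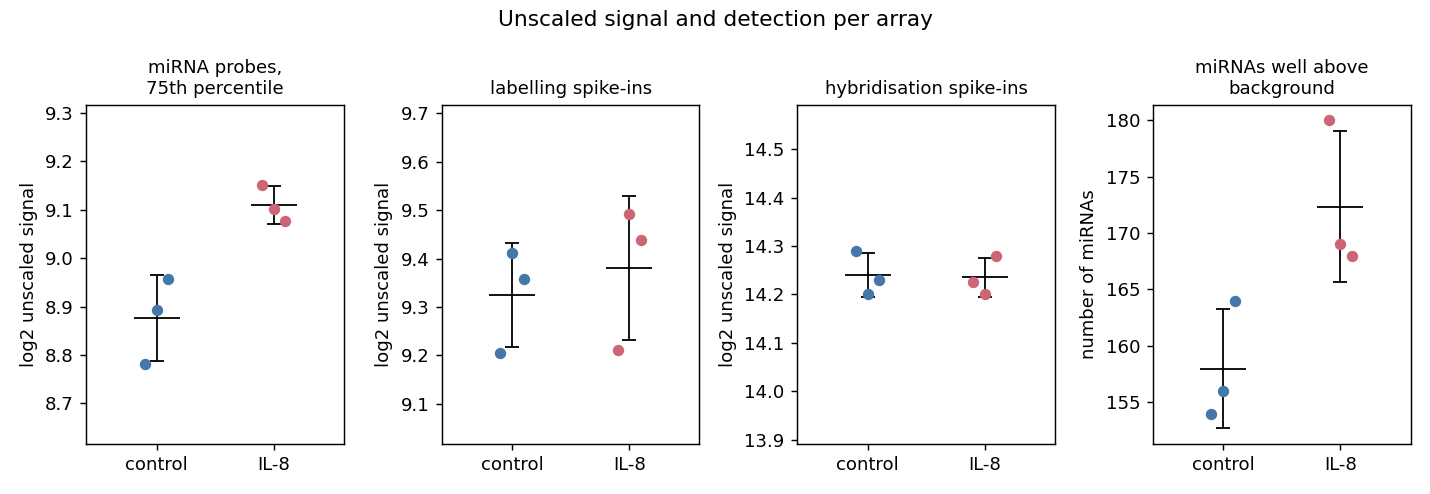
Unscaled log2 signal of the miRNA probes (75th percentile), labelling spike-ins and hybridisation spike-ins, and the number of miRNAs well above background, with 1 point per array and the mean and SD of each group (n = 3). The IL-8 arrays lie above the control arrays in the first panel (9.11 against 8.88 on average) and in the last (172 against 158), and the hybridisation spike-ins average 14.24 in both groups.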

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

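Scaling on labelling spike-ins alone, removal of the probe GC trend and every alternative for the Dlk1-Dio3 median were chosen after the results had been seen. The 10 changed miRNAs kept their direction under all 24 alternatives; miR-210-3p passed in 20 of them, miR-551b-5p in 18, miR-129-1-3p in 17, miR-181a-1-3p and miR-129-2-3p in 16, miR-338-3p and miR-181a-5p in 15, miR-411-3p and miR-132-3p in 13 and miR-6216 in 12. Signal over background limits all values for dim miRNAs. Except where fewer arrays or a different set of tested miRNAs is the alternative's own construction, the cause was not tested.

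Counts of changed miRNAs were 10 as reported, 0 with the 75th percentile over all probes (9 at unadjusted p under 0.05 by limma), 17 with quantile normalization, 51 without scaling, 31 with spike-in scaling, 24 with normexp, 1 with no filter, 28 with array weights and 6 with labelling spike-ins. Counts above 1.5-fold were 1 as reported. They were 0 with the 75th percentile over all probes, median scaling, quantile normalization, normexp, the brightest probe, the filter on all 6 arrays, no filter and the GC trend removed. They were 3 without scaling and with spike-in scaling, and 2 with the software's total gene signal, a lower floor, the series table and labelling spike-ins. The number of lists called was 2 as reported. It was 0 with the 75th percentile over all probes, no scaling, spike-in scaling, labelling spike-ins and an estimated correlation, and 1 with total gene signal, the filter on all 6 arrays, no filter, a lower floor and the series table. That 1 was Dlk1-Dio3, except with no filter, where it was the fibroblast and smooth muscle list. Normexp called 3, the list of miRNAs that promote differentiation, miR-29 and miR-30. Camera sets a list against the other miRNAs, and the median over all tested miRNAs under normexp was -0.070. The Dlk1-Dio3 median was no longer called at 0.0069 with the 75th percentile over all probes, 0.31 without scaling, 0.28 with spike-in scaling, 0.25 with labelling spike-ins, 0 with no filter and 0.074 with an estimated correlation, and it turned to -0.082 with normexp. miRNAs detected in 1 group only numbered 4, 3 with the software's detection call and 1 when every spot had to be above background.

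Leaving out 1 array at a time gave 1 to 29 changed miRNAs, 0 to 1 above 1.5-fold, 0 to 2 lists, 4 to 10 miRNAs detected in 1 group only and a Dlk1-Dio3 median of 0.067 to 0.13. The labelling spike-in difference ran from -0.0037 to 0.14, the hybridisation spike-in difference from -0.026 to 0.021, and the log2 changes of miR-21-5p from -0.070 to 0.098, miR-125b-5p from -0.11 to 0.0070 and miR-322-3p from -0.30 to 0.10.

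With the replicate number as a block, 8 miRNAs were called (3 up, 5 down), 7 of them shared with the fit without the replicate block, so that rises went from 5 to 3. miR-411-3p, miR-181a-5p and miR-132-3p were no longer called and miR-1224, named after its value was seen, was. The miR-30 and Dlk1-Dio3 lists were called (camera adjusted p = 0.0336 and 0.0233). Deviations of samples with the same number correlated at 0.288, 0.330 and 0.0857, and those with different numbers at -0.581 to 0.326. Control replicate 3 correlated best with IL-8 replicate 1 (0.0976). These few values do not decide whether the numbers pair the samples. The block was left out of the main fit because the labels do not say that a number marks a shared culture or day.

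Of 666 values of single named miRNAs under alternatives other than leave-outs, 521 kept direction and side of the threshold, 50 lost and 42 gained a call, and 53 turned sign, none past the threshold. Without scaling the log2 change turned to 0.17 for miR-143-3p, 0.19 for miR-125b-5p, 0.11 for miR-22-3p, 0.20 for miR-23a-3p, 0.071 for miR-222-3p, 0.094 for miR-322-3p, 0.14 for miR-98-5p, 0.16 for let-7i-5p, 0.13 for miR-99b-5p, 0.16 for miR-23b-3p, 0.13 for miR-21-3p and 0.15 for miR-145-5p. With spike-in scaling the same 12 turned, in this order, to 0.15, 0.16, 0.081, 0.17, 0.045, 0.068, 0.12, 0.13, 0.10, 0.14, 0.10 and 0.12, and with labelling spike-ins to 0.12, 0.13, 0.051, 0.14, 0.015, 0.038, 0.089, 0.10, 0.072, 0.11, 0.070 and 0.093. In both spike-in settings and without scaling the median of all miRNAs lies higher (0.21, 0.18 and 0.24). With normexp miR-487b-3p turned to -0.025, miR-25-3p to -0.088, miR-20b-5p to -0.078, miR-15b-5p to -0.0047, miR-34a-3p to -0.074, miR-125a-3p to -0.10 and miR-24-2-5p to -0.010. Under that setting the median of all miRNAs lies lower, at -0.070. With the 75th percentile over all probes miR-21-5p turned to -0.090, miR-25-3p to -0.035, miR-20b-5p to -0.024 and miR-29c-3p to -0.015. miR-21-5p also turned with median scaling (-0.025) and the GC trend removed (-0.042), miR-143-3p and miR-23a-3p with quantile normalization (0.0070 and 0.017), miR-25-3p with the brightest probe (-0.015) and miR-322-3p with array weights (0.036).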

Other observations

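The splits of the arrays, the spike-in and array-wide signals and the settings without scaling and with spike-in scaling were planned. The use of these signals and settings to weigh explanations, and the tests on neighbours, GC content, single probes and muscle-enriched miRNAs, were chosen after the values they bear on had been seen, at least in part. The log2 changes of neighbouring miRNA genes differed less than those of random pairs, with exceptions. miR-34b-5p and miR-34c-5p, side by side on chromosome 8, averaged a log2 change of -0.25, the pair miR-221 and miR-222 on chromosome X averaged -0.13, and 13 precursors between miR-379 and miR-410 on chromosome 6 averaged 0.12. These 13 ranged from -0.068 (miR-494) to 0.32 (miR-376a), and miR-132-3p and miR-212-3p, neighbours on chromosome 10, stood at -0.36 and 0.062. As a hypothesis, shared transcription of clustered genes may underlie this. Over 29 pairs of neighbours within 10 kb in 14 clusters, the mean absolute difference in log2 change was 0.103, against a median of 0.184 for random pairings (one-sided permutation p = 0.0014 with 10000 permutations). It stayed lower without the largest cluster (permutation p = 0.0024) and, in a test added after that value was seen, over the 26 pairs left without neighbours of like name or probe sequence (permutation p = 0.0053). The changes themselves cannot be told apart from a difference between slides.

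The real split of the 6 arrays gave 10 changed miRNAs and the highest of the others gave 0. For changes above 1.5-fold the real split gave 1 and the highest of the others 0, and for lists 2 against 1. In each case 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

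The miRNA probes were brighter on the IL-8 arrays before scaling. A brighter scan or hybridisation of that slide, acting alike at all signal levels, is argued against by the hybridisation spike-ins, which differed by -0.0043 on the log2 scale. The miRNA signal over them was higher by 0.24 ± 0.083 (SE), with an exact permutation p of 0.1. With 1 slide per group this SE holds only the spread between arrays within a slide. At 14.24 the spike-ins also lie far above the miRNA percentile, so a slide difference particular to dimmer signals stays open. A higher labelling yield stays open: the labelling spike-ins differed by 0.056, and the remainder of 0.18 ± 0.11 (SE) is within 2 SE of 0. More miRNA in the RNA of the IL-8 cultures also stays open, since its exact permutation p of 0.1 is the smallest that n = 3 per group allows and slide and group are the same split.

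The 5 falls may reflect, in part, the division by a percentile that was higher on the IL-8 arrays. For miR-210-3p, set apart from the others after its unscaled value had been seen, the unscaled log2 change was -0.27 (limma adjusted p = 0.0464). With spike-in scaling its adjusted p was 0.0647, and over 24 alternatives it ran from 0.000705 to 0.410. Unscaled, miR-6216 had nearly the same change, -0.27 (limma adjusted p = 0.0514), so the threshold alone separates them. The IL-8 mean of miR-210-3p, -4.87, also lay near the floor of -5.03. Whether the division was the whole cause therefore stays open for miR-210-3p. For the other 4 the median unscaled change was -0.24, with a median SE of 0.10 and 0 past the threshold, which leaves the division open as their cause too. Probe GC content as the whole cause is argued against: over the tested miRNAs the change correlated with GC (rho = -0.217, permutation p = 0.00511), yet all 5 falls passed with the GC trend removed. Signal of 1 probe that its partner does not share stays open for the 4 falls that rest on 1 probe, as does an effect of IL-8 itself. Of the falls 80% rest on 1 probe, against 19.1% of the other tested miRNAs and 0 of the 5 rises. Of 75 other miRNAs at or above the level of the 3 brighter of these falls, 2 did. On all 6 arrays 0 of the 4 partners were well above background. Their mean signal, near or below background, was lower with IL-8 for 3 of them, such as that of miR-210-3p (11.8 in control and 9.51 with IL-8). Used and partner probes averaged 89.3 and -0.80 in control for miR-129-1-3p, 91.8 and 6.49 for miR-6216, and 131.5 and 14.6 for miR-129-2-3p.

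The muscle-enriched miRNAs were not above background in cells described as differentiated for 11 days. Weak labelling or degraded RNA is argued against by the 152 of 719 miRNAs well above background on all 6 arrays. Cultures made up mainly of cells other than differentiated muscle cells stay open: 8 of 10 fibroblast and smooth muscle miRNAs were detected, but undifferentiated muscle cells also express members of that list, so this count decides nothing. Those with the highest signal, miR-21-5p and miR-143-3p, had control log2 levels of 4.25 and 3.78, which cannot be set against those of other probes. Probes that fail to bind their targets stay open, since none of the 31 probes was tried here on a sample known to hold these miRNAs.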
